A study of Mus musculus with 76 samples.

How the data were processed

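Libraries were made from DNA digested with MspI, size selected, converted with bisulfite and amplified, per the labels. The deposited files of single libraries hold read counts for each CpG, all reads and methylated reads, on the mouse build mm9. The authors also deposited a table of 100 bp tiles that holds the average methylation of each tile as a fraction. The aligner and read filters are not given in the sources used here, and no molecular identifiers are stated, so that reads may include copies of the same molecule.

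All comparisons were computed from the read counts of the 76 libraries. Libraries whose names differ only by a mark of repetition were taken as the same sample sequenced again and summed, which gave 63 samples, 13 of them from 2 libraries each. For ICM replicates 2, 3 and 4 the libraries differed more than in the other 10 samples, nearly as much as the closest pairs of different ICM samples, so that they may be separate libraries or embryos. CpGs on 19 autosomes and the X chromosome (2352604 in all) were collected into 796484 tiles of 100 bp. The level of a tile is its methylated reads divided by all reads, summed over its CpGs, so that a read over several CpGs counts several times. A tile entered a comparison when it had at least 10 reads in every sample compared. The authors' tile fractions served as a check: in 10 samples, 1 per group, they correlated with the levels computed here with r of 0.993 to 1.0 across tiles, which are not independent replicates. The other 54 sample columns, 1 of them of a sample outside this series, were not used.

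Means over tiles were compared between groups with two-sided exact permutation tests of the samples' means, with Benjamini-Hochberg adjustment over the 10 stage comparisons. Single tiles were tested with a quasi-binomial logistic model of the read counts, written for this purpose in Python, with Pearson dispersions moderated across tiles by the formula of limma's squeezeVar, an F test and Benjamini-Hochberg adjustment. A tile was called at an adjusted p under 0.05 and a difference of group means of at least 20 points. The moderation was checked against limma, and the test was tested on simulated data with known differences. Biopsied and unbiopsied embryos were compared within the cross BDF1xX1 with stage as a covariate; the test of their means used 100000 permutations of the biopsy label within stage. The distance of the zygote from the gamete midpoint has a 95% interval from 10000 bootstraps of the samples of each group. Gamete classes were high at 75% or more and low at 25% or less. Adult tissues (heart, brain, liver) were treated as a single group of 5 samples.

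Tiles named in the text follow a rule: the 3 tiles in each direction with the largest difference among called tiles with at least 3 CpGs, at least 20 reads in every sample and no overlap between the groups, and at most 1 tile per 10 kb. For imprint-like tiles the 5 longest runs with gaps under 1 kb were considered. Lists of genes had also been planned, but gene models on mm9 are not used here, so that tiles are named by position only and no gene list was run. The median number of reads per tile in a sample was 68.0 for oocyte to sperm and 155 for the biopsy comparison, the lowest and highest of the main comparisons.

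These choices, and the alternatives, were set before the data were examined, apart from those named below as chosen later. The alternatives were a minimum of 20 or 5 reads, each CpG counted once, limma on the levels, all tiles of each sample instead of common tiles, libraries as samples, a block for samples that share a number, single crosses, biopsied embryos, class limits of 90% and 10%, and each sample left out in turn. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.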

Results

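The data describe DNA methylation in mouse gametes, embryos and adult tissues, measured by reduced representation bisulfite sequencing. This assay reads single CpGs in the CpG-rich part of the genome that the enzyme MspI releases. The unbiopsied series held 46 samples: 4 of oocytes, 4 of sperm, 4 of zygotes, 4 of 2-cell, 5 of 4-cell and 6 of 8-cell embryos, 5 of the inner cell mass (ICM) of the blastocyst, 4 of embryos at day E6.5, 5 at day E7.5, and 5 of adult tissues (1 heart, 2 brain, 2 liver). A further 17 samples came from embryos whose polar bodies, the small cells that carry the discarded maternal chromosome sets, had been removed by laser biopsy: 5 of zygotes, 4 of 2-cell, 5 of 4-cell and 3 of 8-cell embryos. The embryos came from several crosses, named here as the labels give them; for 3 of the 4 E6.5 samples and all 5 E7.5 samples the labels disagree on the cross, which is not used in the tests at these stages. Levels below are percent methylation of 100 bp tiles in the mm9 build, averaged over the tiles with at least 10 reads in every sample compared. The tile sets differ between comparisons, so that the same group has different means in different comparisons.

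Depth is given as reads summed over CpGs, so that a read over several CpGs counts once at each, in units (M) of 1000000 such observations. The oocyte samples held 22.8 to 69.1 M, the sperm samples 35.9 to 107 M and the unbiopsied zygotes 27.2 to 111 M. The 2-cell samples spread most, from 6.77 to 112 M. The 4-cell samples held 57.3 to 89.2 M, the 8-cell samples 40.0 to 105 M and the ICM samples 23.6 to 92.9 M. Depth was even at E6.5 (57.7 to 61.2 M) and E7.5 (58.2 to 65.8 M). The heart sample held 57.9 M, the brain samples 45.8 and 91.0 M and the liver samples 54.5 and 64.7 M. Biopsied embryos held 50.3 to 85.8 M as zygotes, 38.8 to 74.9 M at 2 cells, 36.0 to 85.5 M at 4 cells and 36.1 to 89.9 M at 8 cells. Between 183675 tiles (a 2-cell sample) and 570500 tiles (a biopsied 4-cell sample) reached 10 reads. Upper limits given below for levels without a methylated read take each observation as a separate count and cover counting error only. Since observations on the same read are not independent and no molecular identifiers are stated for the reads, the true limits may be higher. Bootstrap intervals reflect the variation between samples with the tiles and classes held fixed. With so few samples per group they can be too narrow.

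**Figure D1:**
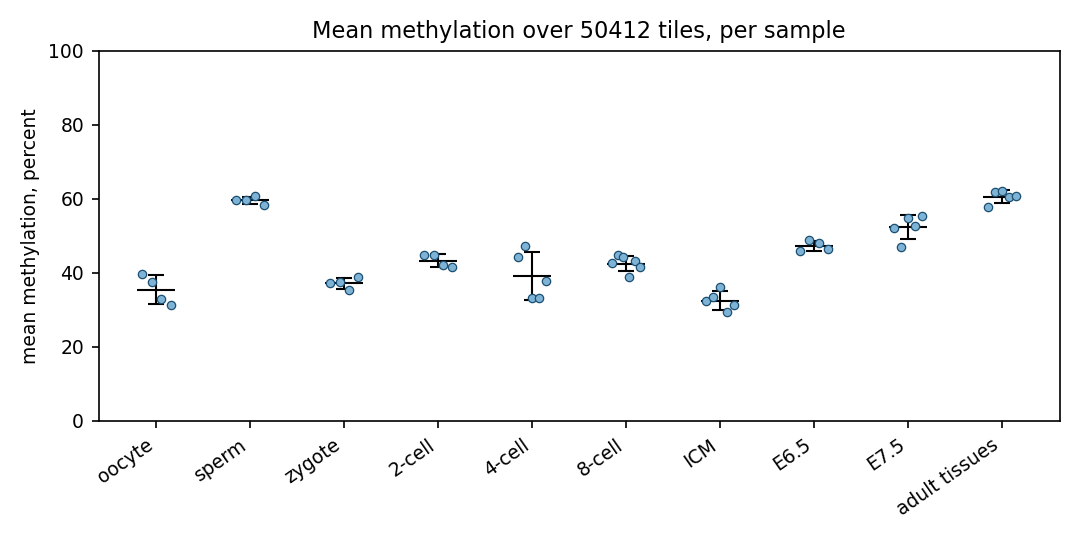
Mean methylation in percent (vertical axis) of each sample, by group (horizontal axis), over the 50412 tiles that reached 10 reads in all 46 unbiopsied samples. Points are samples, the horizontal marks are group means and the bars are SD; the mean fell from 59.5% in sperm to 37.2% in zygotes and was 32.5% in the ICM and 60.6% in adult tissues.

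The comparison of oocytes with sperm asks how the parental genomes differ before fertilization. Sperm were more methylated than oocytes across most of the tiles measured. The mean over 139961 tiles was 36.9% ± 2.28 (SD, n = 4) in oocytes and 67.2% ± 1.76 (n = 4) in sperm, and each of the 4 sperm samples lay above every oocyte sample. Of these tiles, 88405 were higher in sperm and 2100 were lower; the lower count was 6096 without oocyte replicate 1 and 3699 without oocyte replicate 4. The excess in sperm was greatest where CpGs are sparse: 84.1% of tiles with 1 or 2 CpGs were higher in sperm, against 58.1% of tiles with 3 to 5 CpGs and 35.4% of tiles with 6 or more. The largest gains from oocyte to sperm lay on chromosome 18 (83031500 to 83031599, 3 CpGs), from 0.146% ± 0.252 to 98.4% ± 2.501, and at 2 tiles of chromosome 6. These were 118874500 to 118874599 (4 CpGs) and 117224600 to 117224699 (4 CpGs). The first had 0 of 1119 oocyte observations methylated, which allows a level of up to 0.268%, and 98.1% ± 2.503 in sperm. The second went from 0.074% ± 0.148 to 98.2% ± 2.15. The largest losses lay on chromosome 8 (127420600 to 127420699, 3 CpGs), from 99.8% ± 0.243 in oocytes to 0.743% ± 1.26 in sperm, chromosome 18 (23962600 to 23962699, 7 CpGs), from 99.9% ± 0.198 to 0.974% ± 0.681, and chromosome 7 (50721800 to 50721899, 9 CpGs), from 99.6% ± 0.499 to 0.833% ± 0.138. These 6 tiles had at least 32 reads in every sample (n = 4 per group). The exact permutation p of the means was 0.0286, the smallest that 4 against 4 samples can give, and 0.0454 after Benjamini-Hochberg adjustment over the 10 stage comparisons. The oocytes came from several strains (BDF1, ICR, C57B6) and the sperm from X1 and C57B6, so that strain and gamete are partly confounded; at 20 reads per tile, which leaves fewer tiles, 53587 tiles were called.

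The comparisons of each gamete with the zygote ask how much of each parental pattern is present after fertilization. Zygotes lay close to oocytes in their mean and far below sperm. Over 201319 tiles the mean fell from 53.4% ± 1.70 (SD, n = 4) in sperm to 30.2% ± 1.66 (n = 4) in zygotes, with every zygote sample below every sperm sample. In that comparison 93798 tiles were lower in zygotes and 2429 were higher. The share of lower tiles followed CpG density, with 74.3% of the tiles with 1 or 2 CpGs lower, 45.3% of those with 3 to 5 and 18.1% of those with 6 or more. Zygotes also hold the oocyte genome, so that a tile high in sperm and low in oocytes can be lower in zygotes without any loss. The comparison with the gamete midpoint below takes this mixing into account. Over 130396 tiles the oocyte mean was 36.7% ± 2.62 (n = 4) and the zygote mean 38.4% ± 1.93 (n = 4), and 7 tiles were called higher and 30 lower in zygotes. At unadjusted p under 0.05 with the same difference of at least 20 points, 1553 tiles were higher and 2032 lower, and limma on the levels called 9 tiles in all. The exact permutation p was 0.0286 for sperm to zygote (adjusted 0.0454) and 0.4 for oocyte to zygote (adjusted 0.4). On simulated data of the oocyte to zygote design the tile test recovered 58.4% of tiles that differed by 50 points and 8.8% of those that differed by 20. Of its 513 calls there 55 were false, so that the count of 37 can miss tiles and can hold false ones. The simulation gave all tiles the same overdispersion, taken from the oocytes only, so that these shares may not hold for the real data. The count of 37 became 100 without zygote replicate 3, 70 without oocyte replicate 3, 69 without oocyte replicate 1 and 11 without oocyte replicate 4. At 20 reads per tile the counts were 47536 for sperm to zygote and 5 for oocyte to zygote, and over all tiles that reached 10 reads in each sample, rather than shared tiles, the oocyte to zygote difference was -4.37 points (exact p 0.0857); against biopsied zygotes it was 4.15 points (exact p 0.0635).

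Tiles higher in zygotes than in sperm were led by chromosome 10 (45731900 to 45731999, 3 CpGs), from 0.957% ± 1.10 (SD, n = 4) to 93.5% ± 12.6 (n = 4). Next came chromosome 13 (55938500 to 55938599, 6 CpGs), from 3.22% ± 3.10 to 93.9% ± 7.78, and chromosome 4 (101760300 to 101760399, 9 CpGs), from 1.35% ± 0.947 to 91.5% ± 9.98. The tiles furthest below sperm lay on chromosome 6 (113644200 to 113644299, 3 CpGs), chromosome 15 (99622800 to 99622899, 4 CpGs) and chromosome 11 (114236800 to 114236899, 4 CpGs). Each of these had a level of 98.9% in sperm, with SDs of 0.9, 1.52 and 1.09. In zygotes they had no methylated read among 484, 1788 and 1892 observations summed over CpGs, which allows levels of up to 0.62%, 0.168% and 0.159%. From oocyte to zygote, tiles on chromosome 7 (134169500 to 134169599, 16 CpGs), chromosome 9 (108499600 to 108499699, 7 CpGs) and chromosome 13 (99660400 to 99660499, 11 CpGs) fell from 94.9% ± 5.27 to 2.75% ± 5.11, from 97.9% ± 2.70 to 10.6% ± 12.4 and from 97.2% ± 3.00 to 22.8% ± 16.1. In the other direction, 2 tiles met the rule for named tiles, on chromosome 18 (74184100 to 74184199, 3 CpGs), from 0.279% ± 0.559 to 38.4% ± 10.96, and on chromosome 17 (86567300 to 86567399, 5 CpGs), from 0.567% ± 0.738 to 33.2% ± 10.4. These 11 tiles had at least 21 reads in every sample and adjusted p of up to 0.0472.

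A zygote whose genome held both parental patterns unaltered would lie midway between the oocyte and sperm of its parental strains. The gametes here came only in part from those strains. Oocytes were of BDF1, ICR and C57B6, sperm of X1 and C57B6, and zygotes of BDF1xBDF1 and BDF1xX1. Strain is thus partly confounded with any change in these distances and in the gamete to zygote comparisons above. Over 118812 tiles covered in all 3 groups the zygote mean of 38.3% ± 1.94 (SD, n = 4) lay -13.6 points from the midpoint of the gametes (95% bootstrap interval -15.7 to -11.5). The distance depended on which gamete carried the methylation. At 3714 tiles methylated in sperm only (at least 75% in sperm and at most 25% in oocytes) the zygote level was 24.9% ± 3.09 and its distance from the midpoint -25.7 points (-28.6 to -22.9). At 301 tiles methylated in oocytes only the zygote level was 47.9% ± 1.63, and the distance of -0.52 points (-2.67 to 1.43) held no detectable difference. At 4129 tiles high in both gametes the distance was -11.7 points (-13.8 to -9.02), and at 23200 tiles low in both it was -1.31 points (-2.09 to -0.539). At tiles low in both it was -0.414 points (-1.004 to 0.179) with class limits of 90% and 10%, and -0.688 (-1.617 to 0.313) in biopsied zygotes. Since the classes were chosen on the gamete samples that form the midpoint, this choice by itself can push the zygote below the midpoint at tiles high in both. With classes from 2 oocyte and 2 sperm samples and the midpoint from the others, averaged over the 36 such choices, a check added after the data were seen, the distances were 1.84 (-2.10 to 5.32; oocyte-only), -25.9 (-29.2 to -22.7; sperm-only), -7.98 (-11.1 to -4.30; high in both) and -1.80 points (-2.77 to -0.854; low in both). The unbiopsied zygotes could carry polar bodies; in biopsied zygotes (n = 5) the distance was -16.7 points (-19.8 to -13.7) at oocyte-only tiles and -13.9 (-15.9 to -11.9) at sperm-only tiles, and -13.9 (-17.9 to -10.2) and -16.0 (-18.7 to -13.1) with the gamete samples divided in this way. The oocyte-only distance also moved with single samples, with -4.89, -2.35 and -3.38 points without oocyte replicates 1, 2 and 3, -2.36 without zygote replicate 3, and 2.16 and 0.41 without sperm replicates 2 and 4. All of these intervals but that without sperm replicate 4 lay wholly below or wholly above the midpoint.

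The cleavage stages ask whether methylation keeps falling as the embryo divides. It did not fall from zygote to 2-cell: the mean over 114007 tiles was 25.2% ± 1.16 (SD, n = 4) in zygotes and 29.3% ± 1.03 (n = 4) in 2-cell embryos, with each 2-cell sample above every zygote. There, 1205 tiles were higher and 158 lower in 2-cell embryos. From 2-cell to 4-cell the means were 32.5% ± 1.25 (n = 4) and 29.1% ± 5.14 (n = 5) over 98804 tiles, and from 4-cell to 8-cell 33.0% ± 6.97 (n = 5) and 37.1% ± 2.27 (n = 6) over 222106 tiles. The 4-cell samples differed more among themselves than any other unbiopsied group, from 33.1% to 47.2% over the 50412 tiles common to all groups. By exact permutation p was 0.0286 from zygote to 2-cell (adjusted 0.0454), 0.230 from 2-cell to 4-cell (adjusted 0.256) and 0.195 from 4-cell to 8-cell (adjusted 0.243). Without 4-cell replicate 2 the 4-cell to 8-cell difference was 6.33 points with an exact p of 0.0429. Among biopsied embryos the means differed by 0.641 points from zygote to 2-cell (exact p 0.635) and by -2.39 points from 4-cell to 8-cell (exact p 0.446), and over all tiles that reached 10 reads in each sample the zygote to 2-cell difference was 1.73 points (exact p 0.229). Within a single cross, with 2 samples per stage, the zygote to 2-cell differences of 3.595 (BDF1xBDF1) and 3.90 points (BDF1xX1) had an exact p of 0.333, the smallest possible.

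Few tiles passed the test from 2-cell to 8-cell embryos. From 2-cell to 4-cell 5 tiles were higher and 90 lower, and from 4-cell to 8-cell 122 were higher and 11 lower. The 5 tiles higher in 4-cell embryos fall outside the rule for named tiles and were chosen after their values were seen. They lay on chromosome 1 (152875800 to 152875899), from 69.4% ± 17.1 (SD, n = 4) to 99.1% ± 1.30 (n = 5), chromosome 5 (142103800 to 142103899), from 73.1% ± 18.2 to 97.8% ± 3.87, and chromosome 7 (17041400 to 17041499), from 8.26% ± 5.20 to 38.3% ± 10.9. The others lay on chromosome 17 (23260300 to 23260399), from 52.1% ± 5.68 to 83.5% ± 4.44, and chromosome X (16528000 to 16528099), from 62.3% ± 12.8 to 86.5% ± 4.95. These counts moved widely with single samples. From 2-cell to 4-cell no tile passed the quasi-binomial test without 2-cell replicate 3, 150 passed without 2-cell replicate 4, and 253, 31, 37 and 177 without 4-cell replicates 2, 4, 5 and 6. From 4-cell to 8-cell 28, 939, 88 and 295 passed without 4-cell replicates 1, 2, 4 and 6, and 72, 261, 59 and 74 without 8-cell replicates 3, 4, 5 and 8. At unadjusted p under 0.05 and at least 20 points, 3265 tiles were higher and 714 lower from zygote to 2-cell, 162 and 1174 from 2-cell to 4-cell, and 4158 and 1013 from 4-cell to 8-cell; limma called 6, 3 and 2 tiles at the 3 steps, and the quasi-binomial test at 20 reads per tile 683, 12 and 72. From zygote to 2-cell the count of 1363 fell to 657 without 2-cell replicate 3 and to 696 without zygote replicate 3.

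The step from the 8-cell embryo to the ICM was the one preimplantation step after fertilization with a wide loss. The mean over 368441 tiles fell from 34.4% ± 2.67 (SD, n = 6) to 22.3% ± 2.01 (n = 5), with every ICM sample below every 8-cell sample. Here 70727 tiles were lower in the ICM and 31 were higher; the higher count was 60 without 8-cell replicate 2, 63 without 8-cell replicate 3 and 20 without ICM replicate 3. Losses made up 29.3% of tiles with 1 or 2 CpGs, 14.9% of those with 3 to 5 and 4.85% of those with 6 or more. Among tiles methylated in oocytes only, 223 of the 448 tested were lower, against 761 of 5519 methylated in sperm only and 1695 of 6262 high in both gametes. The unbiopsied 8-cell samples could carry polar bodies, so that these counts may not reflect the embryo alone. Class means fell by 21.9 points (oocyte-only) and 12.2 points (sperm-only) from unbiopsied 8-cell samples to the ICM. From biopsied 8-cell samples, over other tiles, the differences were -8.12 and -6.99 points, so that the classes then differed less. The largest losses were on chromosome 4 (129298300 to 129298399, 3 CpGs), from 96.4% ± 4.63 to 16.3% ± 11.1, chromosome 5 (36113800 to 36113899, 3 CpGs), from 82.2% ± 12.4 to 4.58% ± 2.25, and chromosome 16 (13541500 to 13541599, 3 CpGs), from 77.8% ± 11.7 to 8.35% ± 6.13, each with at least 30 reads in every sample. No tile with a gain met the rule for named tiles. Permuting the samples gave an exact p of 0.0022 (adjusted 0.0216). The crosses of the ICM samples differ in part from those of the 8-cell samples, so that cross and stage are partly confounded, and against the 3 biopsied 8-cell samples the ICM difference was -7.45 points (exact p 0.0179).

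The comparison of the ICM with E6.5 asks what the embryo gains at implantation. Methylation rose across most of the genome measured: the mean over 383937 tiles was 21.8% ± 1.86 (SD, n = 5) in the ICM and 49.3% ± 2.05 (n = 4) at E6.5, with every E6.5 sample above every ICM sample. In all, 216437 tiles were higher at E6.5 and 961 were lower. The gain again depended on CpG density, with 80.7% of tiles with 1 or 2 CpGs higher, 51.9% with 3 to 5 and 11.9% with 6 or more. Tiles methylated in sperm only rose in 4790 of 5637 cases, whereas of 454 tiles methylated in oocytes only 45 rose and 56 fell. The largest gains lay on chromosome 8 (90179900 to 90179999, 4 CpGs), from 0.37% ± 0.828 to 92.2% ± 2.53, and chromosome 16 (90524600 to 90524699, 5 CpGs, from 5.78% ± 4.16 to 97.4% ± 2.36, and 90484000 to 90484099, 3 CpGs, from 0.5% ± 1.12 to 91.3% ± 6.73). The largest losses lay on chromosome 13 (114070200 to 114070299, 5 CpGs), from 67.3% ± 14.3 to 1.88% ± 3.75, chromosome 4 (134953900 to 134953999, 3 CpGs), from 70.3% ± 9.44 to 7.19% ± 2.63, and chromosome 5 (137755500 to 137755599, 3 CpGs), from 53.5% ± 9.63 to 2.84% ± 2.90. The exact permutation p was 0.0079 (adjusted 0.0397). The ICM samples include crosses with the strain AJ that the E6.5 labels do not name, but ICM samples of 4 crosses lay between 19.3% and 24.3%, and within the cross BDF1xX1 ICM replicates 4 and 6 had 24.3% and 20.9% and E6.5 replicate 1, the E6.5 sample whose labels agree, 48.4%, so that the gain was also present within a cross, on 1 E6.5 sample. At 20 reads per tile, which leaves fewer tiles, 144514 tiles were called, and with each of the 8 ICM libraries as a sample, over 158555 tiles, the difference of the means was 17.5 points (exact p 0.002).

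**Figure D2:**
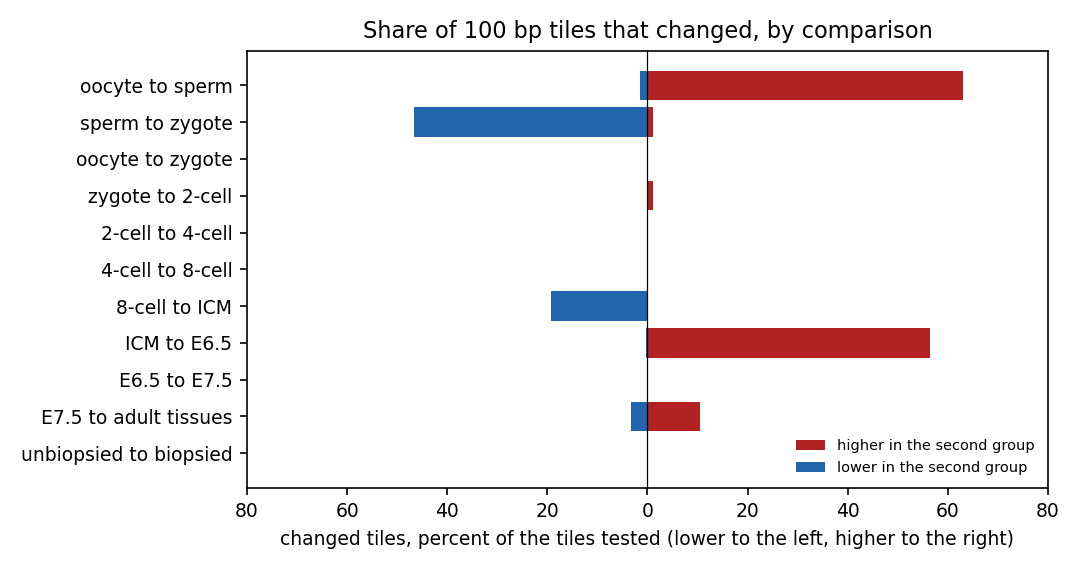
Tiles called changed, in percent of the tiles tested (horizontal axis, lower in the later or named group to the left and higher to the right), for each comparison (vertical axis). Sperm to zygote and 8-cell to ICM were the steps with many lower tiles, at 46.6% and 19.2% of tiles. Zygotes also hold the oocyte genome, so that the sperm to zygote share includes mixing with it and is not loss alone. ICM to E6.5 was the step after fertilization with a wide gain, at 56.4% of tiles.

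From E6.5 to E7.5 the mean rose from 49.96% ± 2.17 (SD, n = 4) to 54.9% ± 2.83 (n = 5) over 436762 tiles, and 4 of the 5 E7.5 samples lay above every E6.5 sample. Single tiles passed rarely: 5 were higher at E7.5 and 0 lower in the quasi-binomial test. At unadjusted p under 0.05 and at least 20 points, 7679 were higher and 170 lower, and limma called 69 higher and 1 lower. The 5 tiles were chosen after their values were seen and lay on chromosomes 7 (26057500 to 26057599), 8 (102884400 to 102884499), 11 (50606200 to 50606299), 15 (101754800 to 101754899) and 19 (50500800 to 50500899). Their levels were 24.98% ± 4.98, 38.3% ± 3.00, 49.9% ± 3.01, 61.5% ± 3.84 and 48.2% ± 8.64 at E6.5 (n = 4) and 48.7% ± 3.38, 64.1% ± 2.72, 80.1% ± 3.79, 85.7% ± 2.73 and 71.3% ± 2.72 at E7.5 (n = 5). The count rested on E7.5 replicate 2, whose mean of 49.9% lay below the other E7.5 samples: without it, 10474 tiles were higher and 115 lower. Without E6.5 replicate 1 12 tiles were called, and none without E6.5 replicate 2 or 4 or without E7.5 replicate 1, 3, 4 or 5. The exact permutation p of the means was 0.0317 (adjusted 0.0454), and it rose above 0.05, up to 0.0893, when any E6.5 replicate but 2 or any E7.5 replicate but 2 was left out. At 20 reads per tile 481 tiles were called.

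The comparison of E7.5 with adult tissues asks how the embryonic pattern relates to that of differentiated cells. The mean rose from 47.8% ± 2.31 (SD, n = 5) at E7.5 to 51.5% ± 1.91 (n = 5) in adult tissues over 296021 tiles. The rise lay in brain and liver, at 51.8% to 53.3%. The single heart sample had 48.2%, within the range of the E7.5 samples (43.7% to 49.4%). Changes went both ways, with 31305 tiles higher and 9685 lower in adult tissues. Gains occurred at 9.95% of tiles with 1 or 2 CpGs, 12.9% of tiles with 3 to 5 and 8.76% of tiles with 6 or more, whereas losses occurred at 5.84%, 3.13% and 0.328% of them. The largest gains lay on chromosome 6 (48388900 to 48388999, 9 CpGs), from 4.97% ± 1.47 to 86.4% ± 11.1, and chromosome 7 (88020600 to 88020699, 9 CpGs, from 4.65% ± 1.41 to 80.8% ± 9.52, and 4982900 to 4982999, 10 CpGs, from 8.30% ± 2.57 to 83.3% ± 3.78). The largest losses lay on chromosome 8 (87223000 to 87223099, 4 CpGs), from 90.4% ± 5.82 to 9.82% ± 3.27, chromosome 10 (77760400 to 77760499, 3 CpGs), from 90.4% ± 3.56 to 10.6% ± 14.1, and chromosome 3 (101973200 to 101973299, 4 CpGs), from 84.1% ± 4.42 to 5.06% ± 5.41. The exact permutation p was 0.0317 (adjusted 0.0454), and it was 0.0556 without brain replicate 2 and 0.0714 without liver replicate 1 or 2. Over all tiles that reached 10 reads in each sample the difference was 0.99 points (exact p 0.619). The adult samples mix heart, brain and liver, and those of different tissues that share a number could come from the same animal. They would then not be 5 independent samples, as both tests take them. Adult samples are labelled BDF1 and the E7.5 labels disagree on the cross, so that strain and stage may be partly confounded.

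Liver and brain differed at single tiles more than in their means. The brain samples had means of 53.1% and 53.2% and the liver samples of 53.5% and 54.6% over 323654 tiles, and 2 against 2 samples cannot reach an exact p under 0.05. The tile test called 6670 tiles higher in liver and 2182 lower.

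Tiles grouped by their gamete levels followed separate courses through development. Over the 50412 tiles covered in all 46 unbiopsied samples, the 173 tiles methylated in oocytes only averaged 89.0% ± 2.26 (SD, n = 4) in oocytes and 47.9% ± 1.43 (n = 4) in zygotes. They had 43.2% ± 6.95 (n = 6) at the 8-cell stage, 21.4% ± 2.68 (n = 5) in the ICM, 13.4% ± 0.516 (n = 4) at E6.5 and 11.7% ± 1.22 (n = 5) in adult tissues. The 1415 tiles methylated in sperm only averaged 88.3% ± 1.99 in sperm, 25.8% ± 2.78 in zygotes, 35.4% ± 3.96 at the 8-cell stage and 23.1% ± 2.71 in the ICM, and they then rose to 57.8% ± 2.72 at E6.5, 68.4% ± 5.33 at E7.5 and 82.6% ± 2.94 in adult tissues. The sperm-only step from E6.5 to E7.5 (10.5 points, adjusted exact p 0.0476) had an adjusted p above 0.05, with differences of 8.61 to 11.4 points, without any single E6.5 replicate (0.0559 to 0.1286), without E7.5 replicate 1, 3, 4 or 5 (0.1209 to 0.1247) and, at 0.0519, without oocyte replicate 4, sperm replicate 3 or zygote replicate 1, 2 or 3. From the zygote on, the 1553 tiles high in both gametes had the highest mean of the 4 classes in every group, with 74.6% ± 2.16 in zygotes, 64.3% ± 4.03 in the ICM, 82.4% ± 1.73 at E6.5 and 89.8% ± 0.41 in adult tissues. The 14745 tiles low in both gametes ranged between group means of 1.69% in the ICM and 4.84% at E7.5. Of 36 tests of class means between successive stages, 24 passed an adjusted exact p of 0.05, among them the loss of oocyte-only tiles from 8-cell to ICM (-21.9 points, adjusted exact p 0.0259) and from ICM to E6.5 (-7.97 points, 0.0259) and the gain of sperm-only tiles from ICM to E6.5 (34.7 points, 0.0259). With biopsied embryos, 3 of them at 8 cells, the 8-cell to ICM step was -8.12 points at oocyte-only tiles and -6.99 at sperm-only tiles (adjusted exact p 0.0643 each). The oocyte-only step from ICM to E6.5 was -2.65 points without sperm replicate 3 (adjusted exact p 0.187), -5.21 with the read minimum in at least 3 samples of each group (0.0519) and -12.5 with class limits of 90% and 10% (0.026). None of the 8 tests from 2-cell to 4-cell and from 4-cell to 8-cell passed, but the sperm-only step from 4-cell to 8-cell did without 4-cell replicate 2 (12.1 points, adjusted exact p 0.0286) and with class limits of 90% and 10% (8.09 points, 0.049). The classes were defined on the same gamete samples that enter the gamete steps, so that those steps are no independent evidence of a change. With the read minimum in at least 3 samples of each group, 10 of the 36 tests passed, and the zygote to 2-cell difference of sperm-only tiles was 2.61 points (adjusted exact p 0.309) in place of 7.16 (0.0448). That difference was 1.65 points with class limits of 90% and 10% (adjusted exact p 0.579) and -4.77 in biopsied embryos (0.149).

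**Figure D3:**
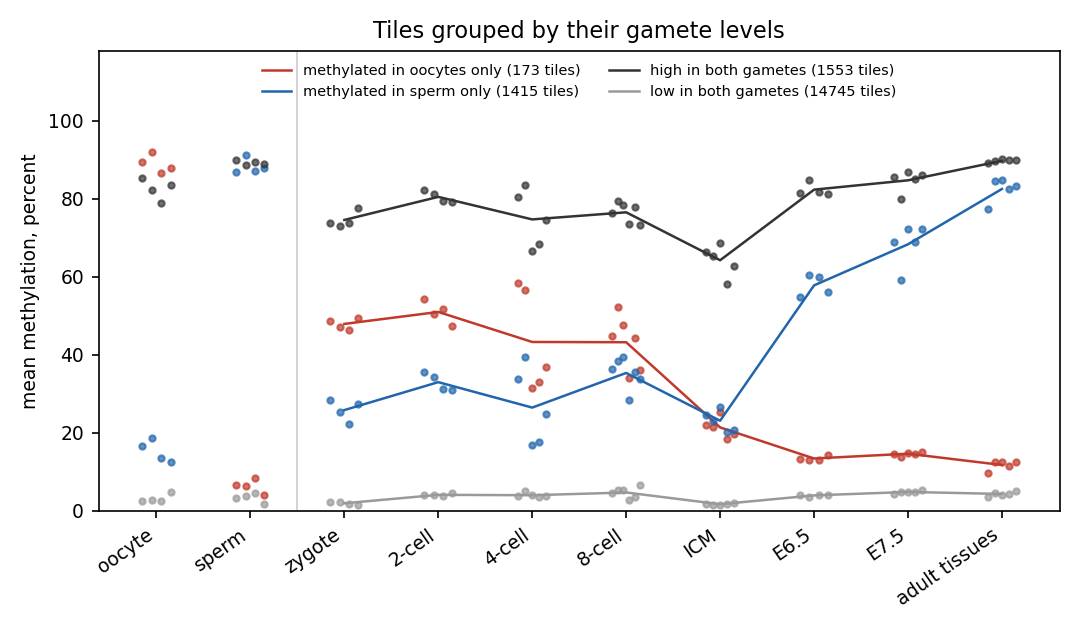
Mean methylation in percent (vertical axis) of tiles grouped by their gamete levels, by group (horizontal axis). Points are samples and lines join the group means from the zygote on; oocyte-only tiles fell to 21.4% in the ICM and 13.4% at E6.5, and sperm-only tiles rose from 23.1% in the ICM to 57.8% at E6.5.

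Levels differed between classes of CpG density, and their order changed with the stage. Tiles with 1 or 2 CpGs averaged 74.5% ± 2.22 (SD, n = 4) in sperm, 31.8% ± 2.86 (n = 5) in the ICM, 63.2% ± 3.30 (n = 4) at E6.5 and 78.1% ± 2.21 (n = 5) in adult tissues. Tiles with 6 or more CpGs averaged 48.2% ± 0.734, 28.1% ± 2.02, 37.6% ± 0.911 and 48.2% ± 1.34 in the same groups. Tiles with 3 to 5 CpGs averaged 73.5% ± 1.21, 39.4% ± 3.38, 58.6% ± 1.74 and 75.6% ± 2.29, and they had the highest mean of the 3 classes in oocytes (42.1%) and from zygotes (44.6%) to the ICM. The classes held 4383 (1 or 2 CpGs), 17980 (3 to 5) and 28049 tiles (6 or more), and no test was run between them.

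Imprint-like tiles were defined as tiles methylated in 1 gamete only that lay between 30% and 70% in the ICM, at E6.5, at E7.5 and in adult tissues, a pattern known from imprinted regions, where methylation of a single parental allele is kept for life. Of 93206 tiles covered in these groups, 18 of 445 oocyte-only tiles (4.04%) and 9 of 4659 sperm-only tiles (0.193%) met this definition. It used group means without a limit on their spread and pooled the adult tissues, so that tiles that differ between tissues or samples can meet it. The longest run held 2 tiles with 14 CpGs on chromosome 10 (12810400 to 12810799), at 94.6% ± 7.67 (SD, n = 4) in oocytes and 14.1% ± 9.98 (n = 4) in sperm. It had 43.0% ± 2.91 (n = 5) in the ICM, 41.7% ± 8.34 (n = 4) at E6.5, 40.7% ± 4.57 (n = 5) at E7.5 and 50.9% ± 3.91 (n = 5) in adult tissues. At the stages that the definition leaves free its levels spread more. They were 45.5% ± 26.1 (n = 4) in zygotes, 67.8% ± 21.2 (n = 4) at 2 cells, 51.3% ± 38.1 (n = 5) at 4 cells and 45.3% ± 12.3 (n = 6) at 8 cells. All other runs held a single tile.

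The biopsied embryos ask what the polar bodies add to the measured methylation. Over all tiles and stages no difference was detectable: biopsied minus unbiopsied embryos of the same cross (BDF1xX1) was -0.432 points over 113037 tiles (17 biopsied and 9 unbiopsied samples, permutation p 0.696, labels permuted within stage). By stage it was 2.38 points in zygotes, -1.34 at 2 cells, 1.80 at 4 cells and -5.40 at 8 cells, with exact p of 0.333, 0.533, 0.679 and 0.1, the last being the smallest that 2 against 3 samples can give. At single tiles 24 were higher and 191 lower in biopsied embryos. Of 223 tiles methylated in oocytes only, 16 were lower and none was higher in the quasi-binomial test. No tile met the rule for named tiles. The count was 43 with limma, 105 at 20 reads per tile and 365 without unbiopsied 4-cell replicate 5, and the mean difference was 0.362 and 0.315 points without unbiopsied 2-cell replicate 2 and 4-cell replicate 2.

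Behind the small mean difference the gamete classes moved in opposite directions in zygotes, in a comparison chosen after the data were seen. At 268 tiles methylated in oocytes only the level was 47.9% ± 1.51 (SD, n = 4) in unbiopsied and 32.6% ± 3.28 (n = 5) in biopsied zygotes, with no overlap between the sets. At 3035 tiles methylated in sperm only it was 26.1% ± 2.79 and 37.3% ± 2.09, again without overlap. Each class had an exact permutation p of 0.0079, or 0.0159 after adjustment over 4 classes. Within the cross BDF1xX1 alone (2 unbiopsied and 5 biopsied zygotes) the differences were -15.3 and 11.9 points, with an exact p of 0.0476 each, the smallest possible, and 0.267 after adjustment over 16 tests. At later stages of that cross the oocyte-only difference was -9.35 points at 2 cells, -5.70 at 4 cells and -13.8 at 8 cells (exact p 0.0667, 0.571 and 0.1), and the sperm-only difference was 2.09, 4.88 and -4.57 points (0.667, 0.411 and 0.2). At 8 cells tiles high in both gametes (-5.47 points) and low in both (-3.26 points) were also lower (exact p 0.1 each). The 8-cell difference was thus not limited to oocyte-only tiles.

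**Figure D4:**
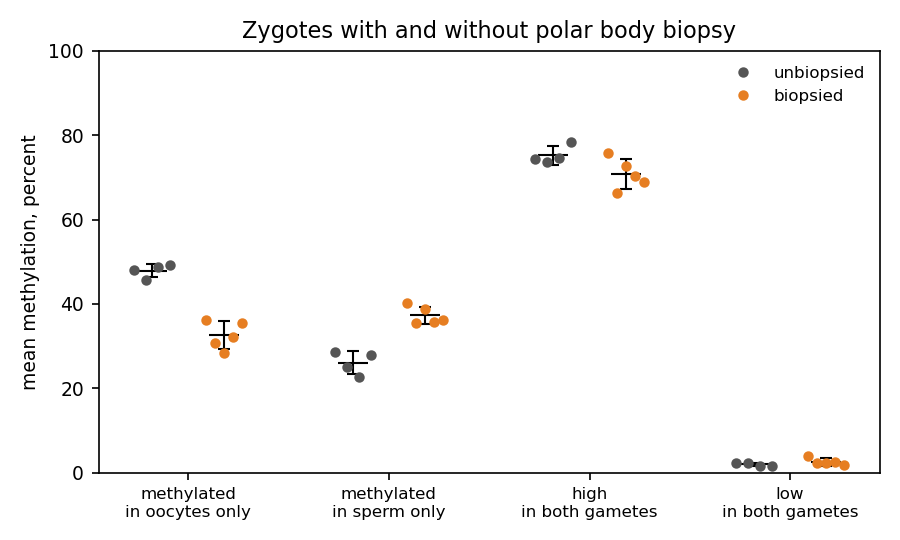
Mean methylation in percent (vertical axis) of unbiopsied (grey) and biopsied (orange) zygotes at tiles grouped by their gamete levels (horizontal axis). Points are samples, the horizontal marks are means and the bars are SD; at oocyte-only tiles the unbiopsied zygotes lay between 45.7% and 49.1% and the biopsied zygotes between 28.4% and 36.2%.

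Embryos of the crosses BDF1xBDF1 and BDF1xX1 had similar means at each stage. The difference, BDF1xX1 minus BDF1xBDF1, was -0.456 points in zygotes, -0.094 at 2 cells, 0.471 at 4 cells and 0.789 at 8 cells (exact p 1.0, 1.0, 1.0 and 0.933), with designs that cannot reach an exact p under 0.05.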

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

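The tests of bisulfite conversion, all tests of explanations for the spread of the 4-cell samples and the test of depth in E7.5 replicate 2 were chosen only after the result was seen, as were the comparison of gamete classes between biopsied and unbiopsied zygotes, the test of depth as the whole cause of it and the use of 109 imprint-like tiles; the biopsied groups were added to the search for samples apart after a first pass. In groups of 4 to 10 samples, each sample at either end was compared with the rest of its group, and 9 of the 82 groups held a sample far from the others. Chance gives about 1 in 20 for a single group of normally distributed values. The groups reuse the same samples over overlapping tiles, and E7.5 replicate 2 alone gave several of the 9. The scan therefore cannot show an excess over chance. None of 15 tests of whether a stage step differed between biopsied and unbiopsied embryos had an exact permutation p under 0.05, with the lowest at 0.102 for sperm-only tiles from zygote to 2-cell (6.78 points unbiopsied, -3.95 points biopsied).

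At tiles methylated in oocytes only, biopsied zygotes averaged 32.6% and unbiopsied zygotes 47.9%, and at tiles methylated in sperm only 37.3% and 26.1%. The tables argue against incomplete conversion, since the classes moved in opposite directions and tiles low in both gametes differed by 0.593 points. Of the unbiopsied zygotes 2 were shallower and 2 deeper than every biopsied zygote, while the sets stayed apart by at least 6.91 points in both classes. The shallow ones were of the cross BDF1xBDF1 and the deep ones of BDF1xX1. These values thus argue against total depth as the whole cause only if the cross has no part. The number of CpGs covered also parted the sets, at 1126713 to 1438241 in unbiopsied and 1552276 to 1729589 in biopsied libraries. What this breadth contributes was not tested. A part due to depth cannot be told apart: thinning every sample to 10 reads per tile moved the differences by up to 2.09 points but also changed which tiles fell in each class, so that it decides nothing. Polar body DNA in the unbiopsied zygotes, which carries the oocyte's pattern, may contribute but cannot be told apart from other causes: at 18 imprint-like oocyte-only tiles the difference was -5.08 points, at the bound of -5 set beforehand, and at 109 such tiles -9.51 points (exact p 0.0238, adjusted over 16 tests 0.152), but the levels of 42.6% ± 8.46 and 37.5% ± 3.20 (109 tiles: 47.3% and 37.8%) lay below 50% and moved away from it, where a level above 50% in unbiopsied zygotes had been set as the mark of polar body DNA. Sperm-only imprint-like tiles, for which no mark had been set, lay nearer 50% in biopsied zygotes. They went from 19.6% in unbiopsied to 36.6% in biopsied zygotes (9 tiles, exact p 0.0317, adjusted 0.152) and from 26.5% to 38.6% (59 tiles, 0.0079, adjusted 0.126). This decides nothing about polar body DNA, since sperm-only tiles as a whole rose too. These tiles were chosen on gametes and on groups from the ICM on, and are not shown to keep a paternal mark in zygotes. In unbiopsied 2-cell embryos the 9 tiles had 54.0%. At later stages the 109 oocyte-only tiles also lay lower in biopsied embryos. At 2 cells they had 56.9% unbiopsied and 45.2% biopsied (exact p 0.0571, adjusted 0.152), the pattern set as the mark in zygotes. At 8 cells they had 53.5% and 36.1% (exact p 0.0476, adjusted 0.152), with the biopsied level further from 50%. At 4 cells the difference was -2.47 points (exact p 0.794). The 18 tiles differed by -6.43, -7.36 and -18.6 points at 2, 4 and 8 cells (exact p 0.114, 0.5635 and 0.0476). Sperm-only tiles did not repeat the zygote gain, and no difference was detectable at these stages. It was -19.7 and -3.58 points (9 and 59 tiles) at 2 cells (exact p 0.143 and 0.629). The values were -0.944 and -0.215 at 4 cells (0.929 and 0.968) and -4.56 and -7.74 at 8 cells (0.548 and 0.286). A biological effect of the biopsy and a difference between batches of embryos were not tested.

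The 4-cell samples ranged from 33.1% to 47.2% over all common tiles, and 4-cell replicate 2 stood apart from the others at tiles low in both gametes (5.02%). The tables argue against incomplete conversion, since tiles low in both gametes spanned 1.44 points, and against the cross, since the samples spanned 11.03 points or more within each cross. They also argue against polar body DNA and against somatic cells as the whole cause: sperm-only tiles were 17.0 points higher in the sample highest in oocyte-only tiles than in the lowest, and oocyte-only tiles were 23.6 points higher in the sample with the highest mean than in that with the lowest. No biological explanation was tested.

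E7.5 replicate 2 lay below the other E7.5 samples in 4 measures: 49.9% over the tiles shared with E6.5, 43.7% over those shared with adult tissues, 59.3% at sperm-only tiles and 79.9% at tiles high in both gametes. The tables argue against low depth, since its 61.4 M observations (units of 1000000) were not the fewest of the group. An embryo nearer to the E6.5 stage may contribute but cannot be told apart from other causes: the slope of its deviation on the E6.5 difference over tiles, each taken from separate E7.5 samples, was 0.464, between the bounds of 0.2 and 0.5 set beforehand, against -0.046 to 0.054 for the other replicates. Without it the E6.5 to E7.5 comparison called 10589 tiles. Its developmental age is not in the labels, and no biological explanation beyond this was tested.

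Other samples stood apart in single measures. E6.5 replicate 4 had the highest level at oocyte-only tiles (14.2%), and E6.5 replicate 2 the highest at tiles high in both gametes (85.0%). Oocyte replicate 4 had the highest level at tiles low in both gametes (4.77%). The biopsied 2-cell replicate 5 had the lowest level of its group at oocyte-only tiles (35.6%).

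Other splits of the same samples show how many tiles a division without regard to stage or biopsy calls. Only the real split, 1 of 35, called as many tiles from oocyte to sperm (90505, highest of the other splits 6) and sperm to zygote (96227, highest other 1). So it was for oocyte to zygote (37, highest other 5) and zygote to 2-cell (1363, highest other 454). This share is the smallest that 4 against 4 samples can give. For the other comparisons 100 of the possible splits were drawn, so that splits left out could call more. Only the real split called as many for 8-cell to ICM (70758, highest other 46962) and ICM to E6.5 (217398, highest other 203459). It was also alone for E7.5 to adult tissues (40990, highest other 10101) and biopsied against unbiopsied embryos (215, highest other 178). The margin was narrow for 4-cell to 8-cell (133, highest other 127). Shares were not adjusted over the comparisons. Some of these counts are not firm: limma called 9 tiles from oocyte to zygote, 6 from zygote to 2-cell, 2 from 4-cell to 8-cell and 43 for biopsy, and the counts were 11 without oocyte replicate 4, 657 without 2-cell replicate 3, 28 without 4-cell replicate 1 (4-cell to 8-cell) and 147 without 8-cell replicate 2 (biopsy), the last 2 below the highest other split of all samples. From E6.5 to E7.5, 3 of 100 splits called as many as the 5 tiles of the real split and the highest called 10879. From 2-cell to 4-cell chance cannot be excluded, since 6 of 100 splits called as many as the 95 tiles and the highest called 2732. Splits that call many times the real count point to a structure of the samples: from 2-cell to 4-cell the splits with 2732 and 1917 tiles parted 4-cell replicates 4, 5 and 6 from 4-cell replicates 1 and 2, and from E6.5 to E7.5 those with 10879 and 9914 tiles put E7.5 replicate 2 with E6.5 samples.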

How the results depend on the processing

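Of 480 recomputed values for 39 results, 385 kept their direction and their side of the threshold or stayed within 1.5 times the count, and 8 changed direction. These totals leave out the 36 single class steps, which were also recomputed and of which some changed direction, as given below. Total counts for 8-cell to ICM, E7.5 to adult tissues and brain to liver stayed within 1.5 times under every alternative run, as did those for oocyte to sperm, sperm to zygote and ICM to E6.5 except at 20 reads. The smaller direction moved more: from oocyte to sperm 2100 lower became 6096 without oocyte replicate 1 and 3699 without oocyte replicate 4, from sperm to zygote 2429 higher became 1213 with limma, from 8-cell to ICM 31 higher became 13 (20 reads) to 63 (without 8-cell replicate 3), and with the block below 961 lower became 1490 (ICM to E6.5) and 9685 lower 5154 (E7.5 to adult tissues; 6335 at 20 reads). The alternatives for imprint-like tiles, biopsied zygotes or divided gamete samples for the midpoint, brain to liver, cross, CpG density and classes with the minimum in at least 3 samples or in biopsied embryos were chosen after seeing the data. The planned gene lists and their alternatives were not run. The cause was not tested for any change below unless it is given.

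At 20 reads, with fewer tiles tested, 53587 tiles were called from oocyte to sperm, 47536 from sperm to zygote, 5 from oocyte to zygote, 683 from zygote to 2-cell, 12 from 2-cell to 4-cell, 72 from 4-cell to 8-cell, 144514 from ICM to E6.5, 481 from E6.5 to E7.5 and 105 for biopsy. At 20 reads the cross difference at 2 cells was 0.125 points, tiles with 1 or 2 CpGs had 28.1% in the ICM and 57.7% at E6.5, and tiles with 6 or more CpGs had 38.8% at E6.5. With limma the counts were 9 (oocyte to zygote), 6 (zygote to 2-cell), 3 (2-cell to 4-cell), 2 (4-cell to 8-cell), 70 (E6.5 to E7.5) and 43 (biopsy). With every library as a sample the biopsy count was 419.

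Sample numbers did not pair samples in any of 10 comparisons (correlations -0.277 to 0.137), so that a block for shared numbers is given only here. With that block the counts were 1266 (oocyte to zygote), 2158 (zygote to 2-cell), 1238 (2-cell to 4-cell), 1706 (4-cell to 8-cell), 0 (E6.5 to E7.5, quasi-binomial test; without the block 7679 higher and 170 lower at unadjusted p under 0.05, and limma 70) and 453 (biopsy). The blocked means differed by 30.3 (oocyte to sperm), -23.2 (sperm to zygote), 4.09 (zygote to 2-cell), -12.3 (8-cell to ICM), 26.9 (ICM to E6.5), 4.73 (E6.5 to E7.5) and 4.71 points (E7.5 to adult tissues), with exact p of 0.125 with 4 pairs and 0.25 with 3 pairs (ICM to E6.5 and E7.5 to adult tissues), the smallest possible, but 0.25 with 4 pairs from E6.5 to E7.5, where 0.125 could have been reached.

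With all tiles of each sample the means differed by -4.37 points from oocyte to zygote, 1.73 from zygote to 2-cell and 0.99 from E7.5 to adult tissues (exact p 0.0857, 0.229 and 0.619). From zygote to 2-cell the difference was 3.595 points in BDF1xBDF1, 3.90 in BDF1xX1 and 0.641 in biopsied embryos, and from 4-cell to 8-cell it was -2.39 in biopsied embryos. Class limits of 90% and 10% put the zygote at -0.414 points from the midpoint at tiles low in both gametes. They also gave 2.81 (oocyte-only, 4-cell to 8-cell), -0.604 (oocyte-only, E6.5 to E7.5), -1.08 (both high, 4-cell to 8-cell) and 0.022 points (both low, 2-cell to 4-cell). With classes from 2 oocyte and 2 sperm samples and the midpoint from the others, the zygote lay 1.84 points from the midpoint at oocyte-only tiles. Biopsied zygotes lay -16.7 points from the midpoint at oocyte-only tiles and -0.688 at tiles low in both. Biopsied embryos gave -4.77 (sperm-only, zygote to 2-cell), -2.32 (sperm-only, 4-cell to 8-cell), -2.92 (both high, 4-cell to 8-cell), 0.085 (both low, 2-cell to 4-cell) and -0.906 points (both low, 4-cell to 8-cell). With the minimum in at least 3 samples of each group 10 class steps passed instead of 24; of the 14 others, 8 had an adjusted exact p of 0.0541, 7 of them at the smallest p of 4 against 4 samples (0.0286) and 1, sperm-only tiles from E6.5 to E7.5, at 0.0238 with 4 against 5 samples, and 6 had other values. Oocyte-only tiles then differed by 4.08 points from 4-cell to 8-cell, and 109 oocyte-only and 59 sperm-only tiles were imprint-like.

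Leaving out each sample in turn gave 11 to 100 tiles from oocyte to zygote, 657 to 1942 from zygote to 2-cell, 0 to 253 from 2-cell to 4-cell, 28 to 939 from 4-cell to 8-cell, 0 to 10589 from E6.5 to E7.5 and 147 to 365 for biopsy; the 0 counts are from the quasi-binomial test, and with all samples 162 tiles were higher and 1174 lower from 2-cell to 4-cell, and 7679 and 170 from E6.5 to E7.5, at unadjusted p under 0.05 (limma 3 and 70). The means differed by 2.56 to 6.33 points (4-cell to 8-cell), 4.26 to 6.16 (E6.5 to E7.5), 2.68 to 4.61 (E7.5 to adult tissues) and -1.06 to 0.362 (biopsy), and the oocyte-only distance from the midpoint was -4.89 to 2.16. Class steps ranged from -3.24 to 4.48 points (oocyte-only, 4-cell to 8-cell), -3.79 to 0.255 (oocyte-only, E7.5 to adult tissues), -0.153 to 4.03 (both high, 4-cell to 8-cell) and -0.359 to 0.047 (both low, 2-cell to 4-cell). What depth limits was not isolated: on simulated data the tile test recovered 8.8% (oocyte to zygote), 12% (8-cell to ICM), 42.2% (E7.5 to adult tissues) and 40.6% (biopsy) of differences of 20 points, with overdispersion of 0.0843, 0.097, 0.0195 and 0.0805 and a median of 77.0, 91.0, 100 and 155 reads per tile. Each overdispersion was the same for all tiles and came from the first group only (unbiopsied embryos for biopsy). Variation between adult tissues was thus not simulated, and the shares may not hold for the real data.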

Other observations

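The X chromosome comparison and the tests of imprint-like tiles below were chosen after seeing the data. With the read minimum asked of at least 3 samples of each group, 109 of 2116 oocyte-only tiles (5.15%) and 59 of 21181 sperm-only tiles (0.279%) were imprint-like, and 31 of the oocyte-only tiles formed 11 runs of 2 or more. No sperm-only tile lay in such a run. The longest runs held 5 tiles each, on chromosome 11 (22871900 to 22874199, 28 CpGs) and chromosome 2 (174123500 to 174124999, 35 CpGs). The run on chromosome 11 had 89.2% ± 13.3 (SD, n = 4) in oocytes, 17.8% ± 7.31 (n = 4) in sperm, 44.0% ± 7.02 (n = 5) in the ICM and 50.4% ± 4.02 (n = 5) in adult tissues. That on chromosome 2 had 98.5% ± 2.51, 15.5% ± 14.5, 46.6% ± 4.83 and 50.9% ± 4.87 in the same groups. Runs of 3 tiles lay on chromosome 10 (12810400 to 12810999), chromosome 15 (89255600 to 89256099) and chromosome 2 (152512500 to 152512899).

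On the X chromosome, methylation was higher than on the autosomes in every group, over 3574 and 46838 tiles common to all unbiopsied samples. The difference, X minus autosomes, was 21.4 points ± 0.695 (SD, n = 4) in sperm, 12.4 ± 2.16 (n = 4) in oocytes, 13.9 ± 0.557 (n = 4) in zygotes, 12.1 ± 1.04 (n = 5) in the ICM, 15.3 ± 0.487 (n = 4) at E6.5 and 20.97 ± 0.74 (n = 5) in adult tissues. The tiles were not matched for CpG density, and no test was run.

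Tile levels of samples of the same group correlated more closely after implantation, with r across tiles of 0.934 to 0.963 at E7.5, than at 4 cells, with r of 0.596 to 0.701. Libraries sequenced again gave r of 0.942 to 0.975 across tiles with their partner in 10 of 13 samples, with a variance 1.23 to 1.43 times the binomial. In ICM replicates 2, 3 and 4 the pairs had r of 0.876, 0.875 and 0.886 and a variance of 2.46, 2.44 and 2.12 times the binomial, against 2.68 to 7.55, 2.43 to 5.41 and 2.43 to 4.28 times to the other ICM samples, so that they match at most the closest of these. Tiles are not independent replicates.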
